A study of Oryza sativa with 9 samples.

How the data were processed

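Total RNA of rice adventitious root segments was hybridised to 9 Agilent rice 44K arrays, 3 per region, with aerated roots in Cy3 and stagnant roots in Cy5 on every array, per the labels. The seedlings were 9 days old when they were transferred to aerated or stagnant solution and 23 days old at harvest. Per the labels' protocols, 400 ng of total RNA was labelled per sample and 825 ng of cRNA of each dye was hybridised. Those protocols speak of a further root region, which was not analysed here.

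Per the file headers and the submitters' processing notes, the arrays were read with Agilent Feature Extraction 10.5.1.1. The deposited spot intensity values were the mean pixel brightness of each spot, the median brightness of its local background, and the processed signal, from which Feature Extraction had subtracted background and which it had normalized between the dyes, per the file headers. The deposited LogRatio is the log10 ratio of the processed Cy5 and Cy3 signals, per the file headers. Of the authors' deposited value table, 8 of the 9 columns equalled this log10 ratio in all 45151 values within a tolerance of 1e-09 and had a median of 0, so that their scale, centring and direction are those of the scanner's ratio. The column of region I replicate 1 equalled the deposited error of the log ratio instead, in 100% of values, with a median of 0.0711, and it was left out where the value table served as an alternative.

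Each array had 45151 spots, of which 1417 were controls and 590 were further negative controls, and the other 43144 held 42418 probes, 534 of them on more than 1 spot. Of these probes, 41889 were paired with 1 locus by the array annotation, which gave 29689 loci. The gene table of the current reference matched 0 of 29689 loci by name or accession, so names and descriptions are those of the array design and can be old. Between 8 and 20 outlier spots per array were dropped, and no spot was saturated.

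Background was corrected with normexp (offset 50) on all spots, and log2 ratios were normalized by loess within each array with controls at weight 0. Spots of 1 probe were averaged. A probe was tested if at least 1 channel was well above background on all 3 arrays of at least 1 region and at least 2 arrays of each region had a value. limma was fitted to all 9 arrays with 1 coefficient per region, followed by eBayes (prior degrees of freedom 2.41), and a call is an adjusted p (Benjamini-Hochberg) under 0.05 over 34713 probes. Differences between regions were contrasts of the same fit. Changes along the root used both channels separately, after Aquantile normalization between arrays, with lmscFit and a spot correlation of 0.257 estimated from 5000 spots. Log ratios of arrays of the same region had correlations across probes of 0.89 to 0.96. The tools were R 4.3.3, limma 3.58.1, statmod 1.5.0 and jsonlite 2.0.0, with version 1.17.8 of the data.table package.

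Where a gene was well above background on no array of a group, a bound is given. It sets the mean of the brighter group against the mean, over the arrays of the dim group, of the higher of the lowest signal well above background and the probe's own signal, per channel after loess and Aquantile, and it is open to dye bias. Of the 24106 genes, 1681, 1508 and 1034 were measured only in stagnant roots of regions I, II and III, 210, 269 and 221 only in aerated roots, and 1236, 663 and 361 in neither. With such genes at their bounds, the medians of lists called in the report were 0.59 for fermentation, 0.37 for glutathione S-transferase and 0.20 for WRKY genes in region I, 1.36 for jasmonate and 0.56 for WRKY genes in region II and 0.94 for jasmonate genes in region III, and those of the other lists called in regions or in differences did not move. Along the root such medians were -1.81 for expansins and -0.54 for peroxidases in aerated and 0.76 for phenylpropanoid genes in stagnant roots, and the others given did not move. Members with no usable bound, such as 4 of 14 suberin genes for regions III and I, kept their fitted value.

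A gene's value is that of its probe with the highest mean log2 intensity over all arrays. Of 6730 genes with several tested probes, 134, 136 and 105 had probes called in opposite directions in regions I, II and III, which is 2.84%, 2.59% and 1.99% of those with a call. Among named genes, the probes of ADH1 ranged from 1.97 to 3.10, from 1.77 to 3.05 and from 1.47 to 2.23 in regions I, II and III, those of PDC1 from 0.86 to 2.08, from 0.59 to 1.61 and from 1.00 to 2.17, and those of SUS1 from 0.58 to 1.69, from -0.74 to 0.17 and from -0.76 to -0.01. The range was 2.99 to 4.31 for the WRKY gene Os01g0734000, 7.51 to 8.64 for the peroxiredoxin Os07g0638400 and 0.33 to 1.11 for the phosphate transporter Os03g0150600 in region I. In region II it was 1.27 to 2.13 for that transporter, -1.25 to -0.39 for the isocitrate lyase family gene Os12g0189300 and 5.51 to 7.40 for the type 3 metallothionein.

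Genes were named by a rule fixed in advance. It takes per region the 10 largest rises and the 10 largest falls among described genes with a call, at least 2-fold and with the same sign on all 3 arrays, up to 2 rising and 2 falling members of each list per region, 19 anchor genes whatever their values, the 10 largest changes per difference between regions, and 5 per direction along the root. Genes measured in only 1 treatment are ranked by their bound, and the text names a part of these genes. Descriptions that read as no hit were counted as uninformative after the descriptions had been seen.

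There were 34 gene lists, built from patterns in the descriptions and from loci, and 30 had at least 5 tested members. They were tested with limma's camera with a preset correlation of 0.01, adjusted over all lists and the 3 regions together, and again with an estimated correlation, with which 1 list, iron deficiency, kept its call in each region. Camera was applied in the same way to differences between regions, a step chosen after the data had been seen, and members were counted in changes along the root. The cell cycle list stands for dividing cells, the secondary wall cellulose synthase list for xylem, and the root hair and photosynthesis lists for root hairs and shoot tissue.

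The arrays lay on 3 slides. Slide 1 held replicate 1 of region I, slide 2 the other 2 replicates of region I and replicates 1 and 2 of region II, and slide 3 replicate 3 of region II and all of region III. Results are therefore also given with the slide as a block and within slides 2 and 3. In slide 3 the lone array of region II is assumed to vary like those of region III. The replicate numbers come from the labels, and arrays of the same number deviated together from their region means: all 9 pairs had a correlation above 0.1, with a lowest value of 0.105 that only just passed, a median of 0.429 and a highest of 0.659, against a median of -0.165 for other pairs. A fit with the replicate number as a block was an alternative planned in advance.

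The fits were tested on simulated data of 34686 probes at the real spread. Of these, 67, 67 and 66 had a log2 change of 0.5, 1 and 2. In region III 52.24%, 83.58% and 96.97% of them were recovered, with 10 unchanged probes called. For regions III minus I the shares were 14.93%, 70.15% and 89.39%, with 4 such calls. Along aerated roots they were 44.78%, 82.09% and 96.97%, with 11 such calls. A further simulation there, with the intensity spread over all arrays halved in place of that within regions, gave 16.42%, 61.19% and 87.88%, with 23 such calls. In these comparisons 46.96% to 76.28% of real probes were called, so the shares need not hold there. Of 30 simulated lists of 40 uncorrelated genes, the 1 shifted by 0.5 was called, so correlated lists stay untested.

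The alternatives were the processed signals, no background correction, median centring alone, scaling between arrays, no filter or a stricter one that asked for both channels above background, outlier spots kept, only the arrays compared, array weights, the replicate or slide block, the value table, a 2-fold minimum, quantile normalization for changes along the root, other list tests and each replicate left out in turn. In all 109 pairs of result and alternative were planned, and 19 were added after the data had been seen: the value table with its error column, the arrays within 1 slide, the slide block for lists and changes along the root, the photosynthesis list without plastocyanin-like members, and other settings for lists in differences and along the root.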

Results

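Adventitious roots of rice (Oryza sativa, cultivar Nipponbare) were compared after 14 days in stagnant, deoxygenated solution, which held 0.1% agar and at most 0.5 mg of oxygen per litre, and in aerated solution. The roots were 100 to 150 mm long and were taken from plants 23 days old. The 3 consecutive segments studied were region I (0 to 10 mm from the apex), region II (10 to 20 mm) and region III (20 to 30 mm). The study asked which genes are expressed while rice roots form a barrier to radial oxygen loss, the escape of oxygen from the root into its surroundings. Each of 9 arrays with 2 colours held Cy3-labelled RNA of aerated roots and Cy5-labelled RNA of stagnant roots of the same region, with 3 biological replicates per region. The median spot intensity per array was 393 to 503 in Cy3 and 663 to 835 in Cy5, against a median local background of 27.5 to 45 and 56 to 60. The Cy3 background was 27.5 to 28 on slide 3, which held all of region III, and 37.5 to 45 on the other slides. Between 67.1% and 77.3% of spots were well above background in Cy3, and between 75.2% and 80.8% in Cy5. In all, 34713 probes were tested, which gave 24106 genes, each represented by its brightest probe. Values are log2 ratios of stagnant over aerated signal with the standard error of the limma fit, over 3 arrays per region. Every p is the adjusted p of limma or, for gene lists, of its camera test. The labels call the replicates biological, so p measures the spread between separate samples, and the small number of arrays limits its precision. No dye was swapped, so the response within a region includes any dye bias of single probes. A bias that is equal on all arrays cancels in differences between regions.

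In region I, which holds the root tip, stagnant roots had far more mRNA of an alternative oxidase, of single peroxidases and of 2 anchor genes of suberin synthesis, and far less mRNA of single genes of iron acquisition. Os02g0318100, the gene of this mitochondrial oxidase, which bypasses the later steps of the cytochrome pathway, rose by 8.37 ± 0.07 (adjusted p = 1.09e-10). CYP86B3 (Os10g0486100), a cytochrome P450 that oxidises fatty acids, rose by 6.08 ± 0.20. RCN1/ABCG5 (Os03g0281900), an ABC transporter that rice roots need for suberin in their outer cell layers, rose by 5.61 ± 0.17. The largest fall among described genes was that of NAS1 (Os03g0307300), which makes the metal chelator nicotianamine, with a log2 ratio of -9.98 ± 0.14 (adjusted p = 9.01e-10). These 4 values were 8.39, 5.94, 5.46 and -10.22 with the slide as a block. They were 8.37, 6.06, 5.65 and -9.94 within slide 2.

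Among the other 9 of the 10 largest described rises in region I were the peroxidases Os03g0339400 (7.76 ± 0.21), Os03g0369000 (7.55 ± 0.30) and Os07g0531400 (7.38 ± 0.13). The peroxiredoxin Os07g0638400 (7.51 ± 0.15) and the serine acetyltransferase Os01g0720700 (6.87 ± 0.12), of cysteine synthesis, were others. The glutathione S-transferase Os09g0367700 was not well above background in aerated roots and was at least 248-fold higher in stagnant roots (adjusted p = 1.15e-07). The largest falls after NAS1 included the oligopeptide transporter Os02g0650300 (-8.81 ± 0.09), a further nicotianamine synthase, Os03g0307200 (-7.09 ± 0.07), the oxalate oxidase Os08g0189300 (-6.83 ± 0.26) and the iron transporter IRT1 (Os03g0667500, -6.15 ± 0.09). The sulfotransferase Os08g0297800 was not well above background in stagnant roots and was at least 89.2-fold lower there. RCN1/ABCG5, Os03g0339400 and Os03g0369000 were well above background on 1 of 3 aerated arrays of region I, and Os07g0531400 and Lsi2 on 2. On stagnant arrays Os08g0189300 was so on 1 and IRO2 on 2.

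Of the 13 genes of the iron deficiency list, 10 fell and 2 rose in region I, with a list median of -4.37 (adjusted p = 2.28e-07, and adjusted p = 0.0304 with an estimated correlation). The iron regulator IRO2 (Os01g0952800) fell by 3.69 ± 0.06, while the nicotianamine synthase Os07g0689600 rose by 2.00. The list median was -4.34 both with the slide as a block and within slide 2. Of the 18 aquaporins and silicon transporters, 16 fell and the other 2 did not pass, with a median of -1.0 (adjusted p = 7.96e-07, and adjusted p = 0.167 with an estimated correlation). The tonoplast aquaporin Os01g0232000 had a log2 ratio of -3.12 and the silicon channel Lsi1 (Os02g0745100) one of -2.24 ± 0.08. The silicon exporter Lsi2 (Os03g0107300) fell by only 0.40 ± 0.15 (adjusted p = 0.0492, but 0.175 without region I replicate 2 and 0.274 without replicate 3). The aquaporin median was -0.96 with the slide as a block and -0.91 within slide 2.

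The fermentation, phenylpropanoid and glutathione S-transferase lists were shifted up in region I, though not with an estimated correlation. Of 12 fermentation genes, which regenerate NAD in low oxygen, 7 rose and the other 5 did not pass (median 0.81, adjusted p = 0.0395, and adjusted p = 0.562 with an estimated correlation). The alcohol dehydrogenases ADH1 (Os11g0210300) and ADH2 (Os11g0210500) rose by 2.93 ± 0.52 and 3.07 ± 0.35, and the pyruvate decarboxylase PDC2 (Os03g0293500) by 1.02 ± 0.26. The slide block gave the list an adjusted p = 0.119 and PDC2 a value of 0.71 (adjusted p = 0.0732), and within slide 2 they had adjusted p = 0.0337 and 0.0702. PDC2 did not pass without replicate 1 (adjusted p = 0.0629) or replicate 2 (adjusted p = 0.0694). PDC1 (Os05g0469600) was not well above background in aerated roots and was at least 4.02-fold higher in stagnant roots. Of 43 phenylpropanoid and lignin genes, 22 rose and 7 fell (median 0.31, adjusted p = 0.0395, and adjusted p = 0.511 with an estimated correlation). Cinnamate 4-hydroxylase (Os02g0467600), which acts early in that pathway, rose by 4.05 ± 0.40. Of 59 glutathione S-transferases, 30 rose and 7 fell (median 0.38, adjusted p = 0.00341, and adjusted p = 0.496 with an estimated correlation). Under the slide block adjusted p was 0.011 for phenylpropanoid genes and 0.00387 for glutathione S-transferases, and within slide 2 it was 0.0389 and 0.00544.

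Among regulators in region I, 24 of 51 ERF factors, which act downstream of ethylene, rose and 6 fell (median 0.32, adjusted p = 0.0261, and adjusted p = 0.653 with an estimated correlation). Auxin response genes had 34 of 75 members higher and 11 lower (median 0.19, adjusted p = 0.043, and adjusted p = 0.653 with an estimated correlation). WRKY factors had 29 of 64 members higher and 10 lower (median 0.29, adjusted p = 0.043, and adjusted p = 0.4 with an estimated correlation). The ERF gene Os09g0287000 was at least 14.3-fold higher in stagnant roots, and the WRKY gene Os01g0734000 rose by 4.31. Blocked by slide, adjusted p was 0.0027 for ERF, 0.0181 for auxin and 0.0312 for WRKY genes, and within slide 2 it was 0.0122, 0.0373 and 0.0562. Jasmonate genes had 18 of 34 members higher and 5 lower, which did not pass as a list (adjusted p = 0.0921). They did pass with the replicate number as a block (adjusted p = 0.0166), with the slide as a block (adjusted p = 0.0312) and within slide 2 (adjusted p = 0.0337). Without replicate 1 the WRKY, auxin, fermentation and phenylpropanoid lists had adjusted p = 0.0996, 0.0588, 0.0577 and 0.0577, and without replicate 2 fermentation had adjusted p = 0.0565. Without replicate 3 the ERF and WRKY lists both had adjusted p = 0.0536 and the auxin list 0.082.

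The cell cycle and ribosomal lists were shifted down in region I by small amounts whose direction depended on the scaling. Of 173 genes of the cell cycle, replication and histones, 67 fell and 26 rose (median -0.13, adjusted p = 0.0261, and adjusted p = 0.786 with an estimated correlation), but with arrays centred on their median in place of loess 69 rose and 33 fell. Of 245 ribosomal protein genes, 103 fell and 11 rose (median -0.16, adjusted p = 1.2e-05, and adjusted p = 0.664 with an estimated correlation), but with median centring 153 rose and 18 fell. The slide block gave medians of -0.07 (adjusted p = 0.133) and -0.09 (adjusted p = 0.00162). Within slide 2 they were -0.12 (adjusted p = 0.026) and -0.14 (adjusted p = 3.43e-05), and without replicate 3 cell cycle genes had adjusted p = 0.082.

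In all, 10059 probes were higher and 8916 lower in stagnant roots of region I, 54.66% of those tested, and 2102 and 1399 of them changed at least 2-fold. Adjusted over the list alone, the counts of higher and lower members were the same for the lists named so far except auxin (34 and 12), jasmonate (18 and 6), iron deficiency (2 and 11) and ribosomal proteins (10 and 100). Under the slide block 8555 probes were higher and 7154 lower, and within slide 2 the counts were 7740 and 6641. With median centring 14920 probes were higher and 7962 lower, so that 65.2% of calls were rises against 53% after loess, and the median of all probes moved from 0.023 to 0.155. There, fermentation, phenylpropanoid, ERF, auxin, glutathione S-transferase and WRKY genes no longer passed as lists (adjusted p = 0.287, 0.076, 0.205, 0.134, 0.0727 and 0.559).

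In region II the suberin, phenylpropanoid, jasmonate, WRKY and glutathione S-transferase lists were shifted up in stagnant roots. The iron, aquaporin, nitrogen, cell cycle and ribosomal lists were shifted down, the last with 65 members higher and 60 lower under median centring, and of these 10 lists only iron passed with an estimated correlation. Os02g0318100 rose by 9.65 ± 0.07 (adjusted p = 4.15e-11), and CYP86A1 (Os01g0854800), which oxidises fatty acids for suberin, by 7.38 ± 0.13 (adjusted p = 2.15e-09). NAS1 had a log2 ratio of -10.50 ± 0.14 (adjusted p = 3.84e-10), and CLC-a (Os12g0438600), a chloride channel family gene, one of -6.98 ± 0.17. Under the slide block Os02g0318100, CYP86A1 and NAS1 had log2 ratios of 9.65, 7.39 and -10.54. Within slide 2 they had 9.63, 7.35 and -10.26, and within slide 3, where region II rests on 1 array with a spread taken from region III, 9.69, 7.43 and -10.99. Os02g0318100 and CYP86A1 were well above background on 2 of 3 aerated arrays of region II, as were the metallothionein Os01g0200700 and the reductase Os09g0567500.

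Other large rises in region II were those of a glycine-rich wall protein (Os06g0199000, 7.55 ± 0.30), a type 3 metallothionein (Os01g0200700, 7.09 ± 0.15) and a laccase (Os01g0827300, 7.01 ± 0.16), an enzyme class that polymerises lignin precursors. Among the 10 largest falls was the ACC synthase family gene Os09g0453800 (-6.81 ± 0.10), related to ethylene synthesis. So were the antiporter Os11g0134900 (-7.25 ± 0.13) and the aldo/keto reductase Os03g0237100 (-6.84 ± 0.06), like Os02g0650300 on the iron list. Of the 14 genes of suberin and fatty acid elongation, 10 rose and 1 fell (median 0.67, adjusted p = 0.00543, and adjusted p = 0.167 with an estimated correlation). The fatty acyl-CoA reductase Os09g0567500 rose by 6.69 ± 0.17, CYP86B3 by 5.11 ± 0.20 and RCN1/ABCG5 by 4.23 ± 0.17. Of 43 phenylpropanoid and lignin genes, 33 rose and 5 fell (median 0.94, adjusted p = 6.68e-05, and adjusted p = 0.277 with an estimated correlation), and cinnamate 4-hydroxylase rose by 6.81 ± 0.40. With the slide as a block adjusted p was 0.00731 for suberin and 3.3e-05 for phenylpropanoid genes. Within slide 2 it was 0.0279 and 0.000109, and within slide 3 it was 0.000804 and 7.36e-06.

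Jasmonate genes of region II had 24 of 34 members higher and 6 lower (median 1.49, adjusted p = 0.0131, and adjusted p = 0.733 with an estimated correlation). An oxophytodienoate reductase (Os06g0216300) rose by 4.42 and a ZIM repressor (Os10g0392400) by 4.68. An allene oxide synthase (Os02g0218800), which acts earlier in jasmonate synthesis, had a log2 ratio of -4.43. Of 64 WRKY factors, 40 rose and 9 fell (median 0.67, adjusted p = 0.00341, and adjusted p = 0.273 with an estimated correlation), with Os12g0116700 up by 4.58 and Os05g0129800 at -4.67. Of 59 glutathione S-transferases, 28 rose and 12 fell (median 0.28, adjusted p = 0.043, and adjusted p = 0.653 with an estimated correlation). The call did not hold with the replicate number as a block (adjusted p = 0.0826), without replicate 1 (adjusted p = 0.0527) or without replicate 3 (adjusted p = 0.056). Blocked by slide, adjusted p was 0.011 for jasmonate, 0.000622 for WRKY and 0.0556 for glutathione S-transferase genes. Within slide 2 it was 0.0175, 0.00222 and 0.0668, and within slide 3 it was 0.00109, 0.00194 and 0.0245. Fermentation genes, 8 of 12 of them higher and 1 lower, did not pass as a list (adjusted p = 0.0921) but did with the replicate number as a block (adjusted p = 0.0477). ADH1 and ADH2 rose by 2.56 ± 0.52 and 2.70 ± 0.35 and PDC2 by 1.48 ± 0.26, while PDC1 had 0.95 ± 0.45 (adjusted p = 0.0948). On the 1 array of region II on slide 3 ADH1 had 1.24 and PDC1 1.62.

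Iron deficiency genes of region II had 11 of 13 members lower and 1 higher (median -4.77, adjusted p = 1.26e-07, and adjusted p = 0.0304 with an estimated correlation), with IRO2 at -4.77 ± 0.06 and IRT1 at -5.56 ± 0.09. Of 18 aquaporins and silicon transporters, 15 fell and 1 rose (median -1.13, adjusted p = 1.32e-05, and adjusted p = 0.203 with an estimated correlation), with the plasma membrane aquaporin Os02g0823100 at -2.02, Lsi1 at -2.53 ± 0.08 and Lsi2 at -1.48 ± 0.15. Of 41 genes of nitrate and ammonium uptake and assimilation, 21 fell and 10 rose (median -0.42, adjusted p = 0.0311, and adjusted p = 0.371 with an estimated correlation). A nitrate reductase (Os08g0468100) had a log2 ratio of -6.13 ± 0.18 and a nitrite reductase (Os01g0357100) one of -4.24. An NADH-dependent glutamate synthase (Os05g0555600), which assimilates ammonium, was at least 22.5-fold higher. Of the 173 cell cycle genes, 117 fell and 25 rose (median -0.40, adjusted p = 2.01e-07, and adjusted p = 0.478 with an estimated correlation). Of the 245 ribosomal protein genes, 185 fell and 17 rose (median -0.43, adjusted p = 3.53e-14, and adjusted p = 0.454 with an estimated correlation), although with median centring 65 ribosomal genes rose and 60 fell. The medians of the iron, aquaporin, nitrogen, cell cycle and ribosomal lists were -4.83, -1.08, -0.40, -0.41 and -0.46 with the slide as a block. They were -4.75, -1.21, -0.23, -0.47 and -0.48 within slide 2, and -4.81, -0.91, -0.51, -0.30 and -0.32 within slide 3.

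In region II 12121 probes were higher and 10652 lower, 65.6% of those tested, and 3681 and 2258 changed at least 2-fold. These counts exceeded those of region I, but with only the arrays of each region in its fit region II had 9966 and 8587 and region I 10050 and 8884. The counts adjusted over the list alone were the same for the lists just named except jasmonate (24 higher and 7 lower), glutathione S-transferases (30 and 12), WRKY (40 and 11), cell cycle (25 and 118) and ribosomal proteins (17 and 188). Falls outnumbered rises with the processed signals (10722 higher and 12240 lower, 46.7% rises) and with both channels above background (8857 and 9192, 49.1%). The slide block gave 10988 higher and 9570 lower probes. Within slide 2 the counts were 10358 and 9044, and within slide 3 they were 7331 and 5396. With median centring 65.1% of calls were rises against 53.2% after loess (16112 higher and 8638 lower, median of all probes 0.183 against 0.029). There, the jasmonate, glutathione S-transferase, nitrogen and ribosomal lists no longer passed (adjusted p = 0.118, 0.182, 0.0934 and 0.0655).

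In region III, the segment farthest from the apex, the suberin, phenylpropanoid, NAC, jasmonate and WRKY lists were shifted up in stagnant roots. The iron, aquaporin, nitrogen, ethylene, cell cycle and ribosomal lists were shifted down, and of these 11 lists only iron passed with an estimated correlation. Os02g0318100 rose by 7.91 ± 0.07 (adjusted p = 6.06e-11), CYP86A1 by 7.75 ± 0.13 (adjusted p = 1.93e-09) and the NAC factor Os03g0624600 by 7.04 ± 0.20 (adjusted p = 3e-08). NAS1 had a log2 ratio of -10.98 ± 0.14 (adjusted p = 2.97e-10) and the ammonium transporter Os02g0620600 one of -6.74 ± 0.24. Blocked by slide, Os02g0318100, CYP86A1 and NAS1 had log2 ratios of 7.86, 7.71 and -10.53, and all 3 region III arrays lay on slide 3.

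Other large rises in region III were those of an ABC transporter (Os05g0120200, 7.58 ± 0.27) and of the peroxidases Os12g0112000 (7.23 ± 0.08) and Os07g0677600 (7.16 ± 0.18). The cysteine protease Os01g0347600 (-7.48 ± 0.33), CLC-a (-7.22) and the metal transporter Os07g0258400 (-6.66 ± 0.06) were among the 10 largest falls. Of the 14 suberin genes, 11 rose and 3 fell (median 1.30, adjusted p = 0.00205, and adjusted p = 0.167 with an estimated correlation). The fatty acyl-CoA reductase Os09g0567500 rose by 6.92 ± 0.17, CYP86B3 by 5.55 ± 0.20 and RCN1/ABCG5 by 5.10 ± 0.17. Of 43 phenylpropanoid and lignin genes, 31 rose and 8 fell (median 1.13, adjusted p = 0.00012, and adjusted p = 0.277 with an estimated correlation), with a cinnamoyl-CoA reductase (Os01g0283600), which leads to lignin precursors, up by 5.23. Under the slide block the suberin and phenylpropanoid lists had adjusted p = 0.00162 and 0.00061, and within slide 3 they had 0.00291 and 0.000127. All 4 genes of the secondary wall cellulose synthase list, 3 synthases and BRITTLE CULM1, markers of xylem and other thick-walled cells that had too few members for the list test, rose in region III, and 3 of them fell in region I. CESA4 (Os01g0750300) had log2 ratios of -0.64, 0.15 and 0.66 in regions I, II and III (SE 0.08). It passed in region II only with the replicate number as a block (adjusted p = 0.0468) or without region II replicate 3 (adjusted p = 0.0488). CESA7 (Os10g0467800) had -0.14, 0.82 and 1.15 (SE 0.10). CESA9 (Os09g0422500) had -0.55, -0.16 and 0.25 (SE 0.08), of which the last did not pass without region III replicate 2 (adjusted p = 0.107) or replicate 3 (adjusted p = 0.108). BRITTLE CULM1 (Os03g0416200), which helps to assemble cellulose, fell in region I and rose in region III. Blocked by slide, its values of -0.50 (adjusted p = 0.113) and 0.62 (adjusted p = 0.186) did not pass. Nor did its region I value without replicate 2 (adjusted p = 0.0549) or replicate 3 (adjusted p = 0.124).

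Of 57 NAC factors in region III, 30 rose and 8 fell (median 0.44, adjusted p = 0.0167, and adjusted p = 0.29 with an estimated correlation). Its adjusted p was 0.102 with the slide as a block and 0.0143 within slide 3. Jasmonate genes had 22 of 34 members higher and 5 lower (median 1.00, adjusted p = 0.0283, and adjusted p = 0.786 with an estimated correlation). The list had a median of 0.48 and adjusted p = 0.253 with the slide as a block, adjusted p = 0.00929 within slide 3 and adjusted p = 0.0544 without replicate 3. Of 64 WRKY factors, 39 rose and 12 fell (median 0.72, adjusted p = 0.0142, and adjusted p = 0.298 with an estimated correlation). Their adjusted p was 0.011 with the slide as a block and 0.0069 within slide 3. Of 23 genes of ethylene synthesis and signalling, 13 fell and 6 rose (median -0.54, adjusted p = 0.043, and adjusted p = 0.277 with an estimated correlation). Their adjusted p was 0.0441 with the slide as a block, 0.0265 within slide 3, 0.0578 with the replicate number as a block and 0.0546 without replicate 1. The ACC oxidase Os11g0186900, which makes ethylene, had a log2 ratio of -6.52 ± 0.17 in region III.

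Iron deficiency genes of region III had 12 of 13 members lower and 1 higher (median -4.88, adjusted p = 2.93e-07, and adjusted p = 0.0304 with an estimated correlation). Of 18 aquaporins and silicon transporters, 15 fell and the other 3 did not pass (median -1.23, adjusted p = 1.28e-06, and adjusted p = 0.167 with an estimated correlation), with Os02g0823100 at -3.96, Lsi1 at -3.25 ± 0.08 and Lsi2 at -4.17 ± 0.15. Of 41 nitrogen genes, 21 fell and 10 rose (median -0.29, adjusted p = 0.0238, and adjusted p = 0.333 with an estimated correlation). Asparagine synthetase (Os03g0291500) had a log2 ratio of -6.08 ± 0.16. NAR2.1 (Os02g0595900), the partner of nitrate transporters, had -1.98, -2.58 and -5.24 in the 3 regions (SE 0.46), while the transporter NRT2.1 (Os02g0112100) did not pass in any of them. Of 173 cell cycle genes, 100 fell and 32 rose (median -0.28, adjusted p = 0.0011, and adjusted p = 0.653 with an estimated correlation). Of 245 ribosomal protein genes, 214 fell and 14 rose (median -0.61, adjusted p = 1.74e-20, and adjusted p = 0.333 with an estimated correlation), 9 of the falls at least 2-fold. The medians of the iron, aquaporin, nitrogen, cell cycle and ribosomal lists were -4.87, -1.43, -0.26, -0.33 and -0.72 with the slide as a block.

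In region III 12052 probes were higher and 11048 lower, 66.55% of those tested, and 3987 and 2176 changed at least 2-fold. The counts adjusted over the list alone were the same for the lists just named except for 1 further lower gene each in the WRKY and cell cycle lists. The slide block gave 7990 higher and 7481 lower probes, and within slide 3 the counts were 11432 and 10299. With median centring 65.4% of calls were rises against 52.2% after loess (15712 higher and 8296 lower, median of all probes 0.171 against 0.024). There, the jasmonate, WRKY, NAC and cell cycle lists no longer passed (adjusted p = 0.232, 0.11, 0.108 and 0.0548).

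Of anchor genes of low oxygen metabolism, PPDKB (Os05g0405000), a pyruvate orthophosphate dikinase, rose by 5.69, 5.86 and 2.88 in regions I, II and III (SE 0.32). Sucrose synthase SUS1 (Os03g0401300) rose by 1.52 ± 0.09 in region I and had log2 ratios of -0.43 and -0.44 in regions II and III, which became 0.23 and 0.00 with median centring. They did not pass within slide 2 (adjusted p = 0.0518) and slide 3 (adjusted p = 0.0575) for region II or with the slide as a block for region III (adjusted p = 0.114). The non-symbiotic haemoglobin HB1 (Os03g0233900), which binds nitric oxide and oxygen, had 0.15 and 0.26 in regions I and II, which did not pass. It had -2.42 ± 0.51 in region III, which with the slide as a block was -0.72 (adjusted p = 0.394). In region III ADH1 and ADH2 rose by 1.95 ± 0.52 and 1.88 ± 0.35, PDC2 by 0.93 ± 0.26 and PDC1 by 2.17 ± 0.45. Of these, ADH1 did not pass without replicate 1 (adjusted p = 0.0603), PDC2 not without replicate 1 (adjusted p = 0.0678) or replicate 2 (adjusted p = 0.0505), and PDC1 not with the slide as a block (adjusted p = 0.259). The lactate dehydrogenase Os06g0104900 was not well above background in aerated roots and was at least 21.5-fold higher in stagnant roots of region III. PDC1 was well above background on 2 of 3 aerated arrays there.

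The remaining lists did not pass the list test in the regions named here. Fermentation genes had 8 of 12 members higher and 1 lower in region III (adjusted p = 0.192), suberin genes 8 of 14 higher and 3 lower in region I (adjusted p = 0.237). Nitrogen genes had 12 of 41 higher and 14 lower in region I (adjusted p = 0.639), where the median of 0.05 and the mean of -0.37 differed in sign and median centring gave 17 higher and 13 lower. Of 68 genes of sucrose breakdown and glycolysis, 22, 21 and 15 were higher and 18, 29 and 32 lower in regions I, II and III (adjusted p = 0.858, 0.512 and 0.0893). In region II the median was -0.06 and the mean 0.15, with 33 higher and 16 lower under median centring, which gave 24 and 21 in region III. Of 51 genes of the tricarboxylic acid cycle, 20, 18 and 13 were higher and 13, 17 and 24 lower (adjusted p = 0.405, 0.875 and 0.194). In region II the median was 0.01 and the test pointed down, with 14 higher and 20 lower with the processed signals, and in region III median centring gave 25 higher and 12 lower. Of 6 haemoglobins, 2 were higher in regions I and II, and 1 was higher and 4 lower in region III (adjusted p = 0.364, 0.731 and 0.413). Of 18 lipid transfer proteins and GDSL lipases, which carry or process lipids of the cell surface, 4, 7 and 5 were higher and 5, 8 and 7 lower (adjusted p = 0.764, 0.869 and 0.55). The list had a median of 0.01 (-0.17 under median centring) and a test that pointed down in region I and a median of -0.10 against a mean of 0.51 in region II. Of 15 laccases and dirigent proteins, 2, 6 and 8 were higher and 7, 7 and 1 lower (adjusted p = 0.252, 0.73 and 0.164), with a median of -0.20 against a mean of 0.23 in region II. Of 116 class III peroxidases, 39, 39 and 40 were higher and 31, 36 and 35 lower (adjusted p = 0.883, 0.806 and 0.754). Their medians were -0.08, -0.01 and -0.02 against means of 0.31, 0.47 and 0.42, and 0.04 and 0.15 in regions I and II under median centring. At least 2-fold changes made up 24, 29 and 30 of the rises and 23, 16 and 13 of the falls.

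Of 50 expansins and xyloglucan enzymes, which loosen cell walls, 8, 9 and 13 were higher and 12, 18 and 11 lower in regions I, II and III (adjusted p = 0.4, 0.29 and 0.875), with 18 higher and 8 lower in region I under median centring and an adjusted p of 0.049 in region II within slide 2. Of 57 genes of pectin and cellulose degradation, 11, 15 and 16 were higher and 18, 25 and 21 lower (adjusted p = 0.228, 0.4 and 0.678). Of 18 respiratory burst oxidases and metallothioneins, 6, 8 and 8 were higher and 6 lower in each region (adjusted p = 0.875, 0.976 and 0.883), with 8 higher and 3 lower in region I under median centring. The metallothionein Os12g0568500 was at -5.01 ± 0.15 in region III. Ethylene genes had 5 and 7 of 23 members higher and 7 and 10 lower in regions I and II (adjusted p = 0.28 and 0.252), and under median centring 9 higher and 7 lower in region I. ERF genes had 28 and 23 of 51 members higher and 9 and 11 lower in regions II and III (adjusted p = 0.0921 and 0.192), auxin genes 30 and 29 of 75 higher and 25 and 23 lower (adjusted p = 0.764 in both). NAC genes had 24 and 31 of 57 higher and 7 and 14 lower in regions I and II (adjusted p = 0.114 and 0.0921). Without region II replicate 1 the ERF and NAC lists passed in region II (adjusted p = 0.0451 and 0.0486). Glutathione S-transferases had 25 of 59 members higher and 16 lower in region III (adjusted p = 0.4). Of 28 abscisic acid and dehydration genes, 10, 11 and 9 were higher and 5, 7 and 8 lower (adjusted p = 0.732, 0.976 and 0.875). They had a median of -0.02 (0.29 under median centring) against a mean of 0.17 in region II, a median of 0.04 and a test that pointed down in region III, and 9 higher and 11 lower in region III with the processed signals. Of 31 phosphate starvation genes, 12, 13 and 17 were higher and 6, 5 and 6 lower (adjusted p = 0.4, 0.252 and 0.237).

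Of 146 heat shock proteins, 34, 54 and 45 were higher and 48, 40 and 53 lower in regions I, II and III (adjusted p = 0.213, 0.822 and 0.708). Median centring gave 52 and 64 higher and 28 and 26 lower in regions I and III, and the processed signals 38 higher and 43 lower in region II. Of 64 pathogenesis-related and diterpenoid defence genes, 16, 23 and 29 were higher and 22, 19 and 14 lower (adjusted p = 0.708, 0.875 and 0.274), with a median of 0.04 (-0.03 under median centring) and a test that pointed down in region I. Of 135 MYB factors, 45, 60 and 59 were higher and 34, 37 and 34 lower (adjusted p = 0.64, 0.413 and 0.252). Of 56 photosynthesis genes, markers of shoot tissue, 16, 23 and 22 were higher and 14, 15 and 16 lower (adjusted p = 0.875, 0.806 and 0.648). Here median centring gave 15 and 19 higher and 24 and 20 lower in regions I and II. Lists with under 5 tested members have counts only. Of 4 ferritins, which store iron, 2, 3 and 4 rose and 1 fell in region I. Of 2 root hair genes 1 rose in each region and 1 fell in region II, and no locus matched the Casparian strip list. Adjusted over the list alone, the counts of higher and lower members differed in region I for the tricarboxylic acid cycle (21 and 13), lipid transfer proteins (3 and 5), peroxidases (39 and 33), expansins (8 and 10), pectin (11 and 17) and ferritins (3 and 1). They differed in region II for ERF (29 and 9), defence (23 and 20), NAC (32 and 14), MYB (60 and 38) and photosynthesis genes (24 and 15), and in region III for glycolysis (15 and 33), the tricarboxylic acid cycle (14 and 24), burst oxidases and metallothioneins (9 and 6) and MYB factors (61 and 35).

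**Figure D1:**
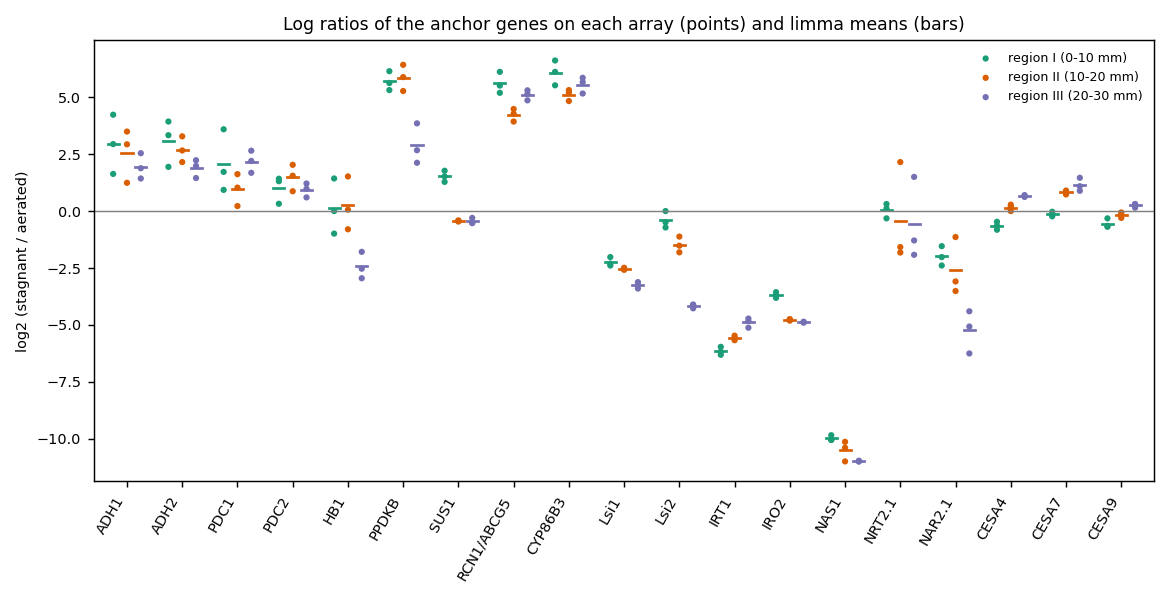
Log2 ratio of stagnant over aerated signal (vertical axis) of the 19 anchor genes in regions I, II and III, with points for single arrays and bars for limma means of 3 arrays per region. CYP86B3 lay highest in regions I (6.08) and III (5.55) and PPDKB in region II (5.86), NAS1 lay lowest with -9.98, -10.50 and -10.98, and SUS1 had 1.52, -0.43 and -0.44, of which the last 2 became 0.23 and 0.00 with median centring.

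**Figure D2:**
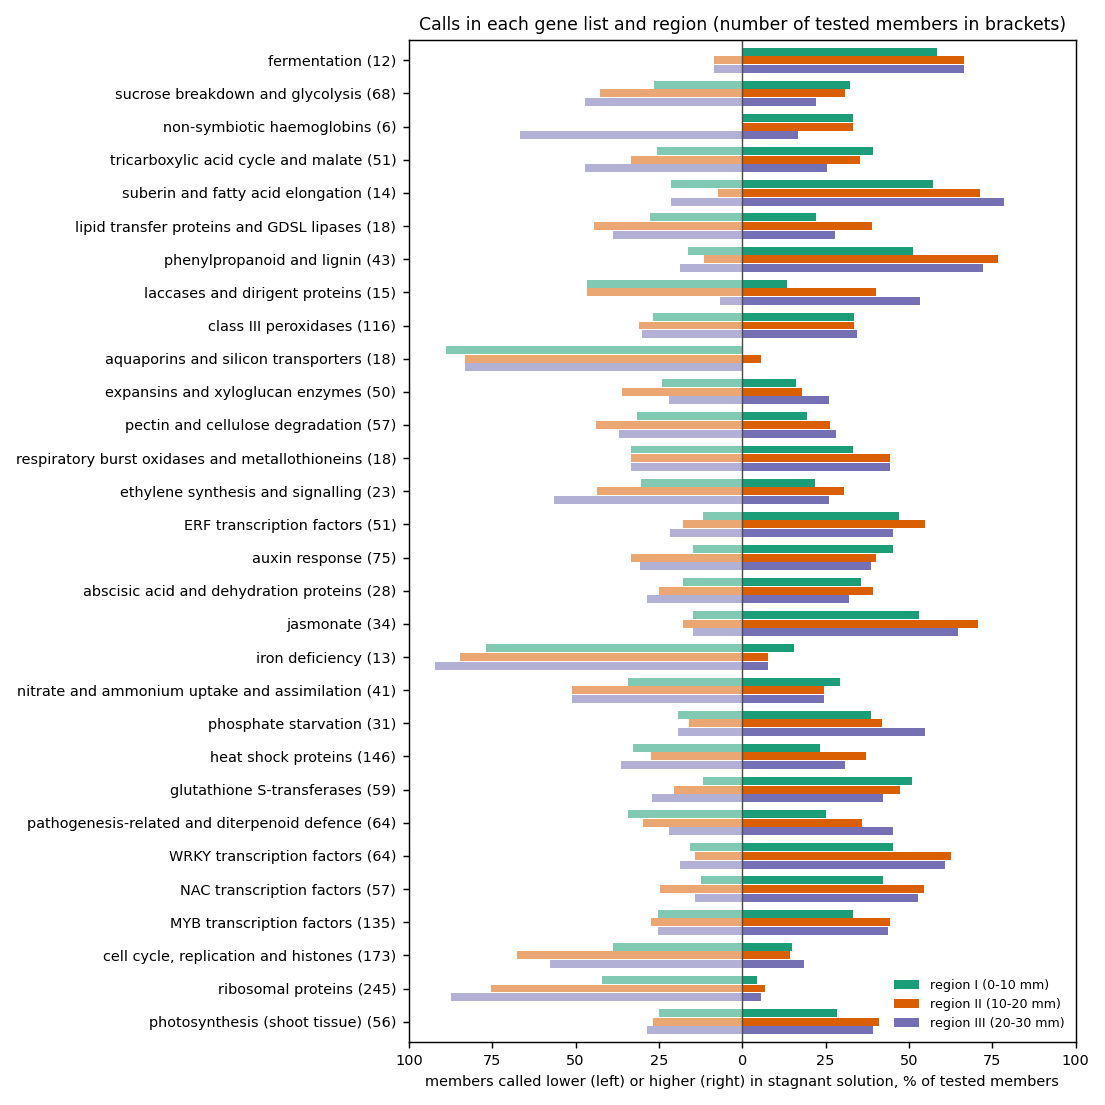
Percent of the tested members of each of 30 gene lists that were called higher or lower in stagnant roots of regions I, II and III, with the number of members in brackets. Of 18 aquaporins and silicon transporters 16, 15 and 15 were lower, and of 245 ribosomal protein genes 103, 185 and 214, although with median centring 153 ribosomal genes were higher and 18 lower in region I, and 65 higher and 60 lower in region II.

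Many probes responded in the same direction in all 3 regions. The number was 5466 for rises and 4750 for falls, where independent lists of these sizes would share 1219.5 and 870.8. Of these, 1115 and 644 changed at least 2-fold in each region, against 25.6 and 5.7. Os02g0318100, CYP86B3, RCN1/ABCG5, ADH1, ADH2, PDC2 and PPDKB rose in all 3 regions, and NAS1, IRO2, IRT1, Lsi1, Lsi2 and NAR2.1 fell in all 3. Across probes, which are not independent replicates, the log2 ratios had a correlation of 0.71 between regions I and II, 0.56 between I and III and 0.87 between II and III. All regions have the same dye layout, so the overlap includes any dye bias of single probes. The slide block left 3389 probes that rose and 2995 that fell in all 3 regions, and with median centring 9477 rose.

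Whether the response depended on the position along the root was tested as the difference between log2 ratios. From region I to region II the response of the phenylpropanoid list was shifted up and those of the iron, cell cycle and ribosomal lists down, none of them with an estimated correlation. A GDSL lipase (Os03g0310000) went from -3.68 to 3.21, a difference of 6.89 ± 0.28 (adjusted p = 2.34e-06), and the root gene RCc2 (Os10g0552300) from -1.81 to 4.12. A Nodulin 21 family gene (Os04g0538400) went from 5.08 to -1.55, a difference of -6.63 ± 0.42 (adjusted p = 1.56e-05), the germin Os08g0231400 from 2.05 to -4.23 and the peroxidase Os03g0369000 from 7.55 to 1.65. With the slide as a block the first differences named, of Os03g0310000, RCc2 and Os04g0538400, were 7.24, 5.35 and -6.87. Of 43 phenylpropanoid genes, 23 had a higher and 5 a lower response in region II (median difference 0.66, adjusted p = 0.00184, and adjusted p = 0.548 with an estimated correlation). Of 13 iron deficiency genes, 7 had a lower and 2 a higher one (median -0.76, adjusted p = 0.00604, and adjusted p = 0.548 with an estimated correlation). Cell cycle genes had 70 of 173 members lower and 15 higher (median -0.24, adjusted p = 0.000127, and adjusted p = 0.671 with an estimated correlation), and ribosomal proteins had 115 of 245 lower and 15 higher (median -0.28, adjusted p = 1.22e-07, and adjusted p = 0.671 with an estimated correlation). Blocked by slide, these 4 lists had adjusted p = 0.0101, 0.0168, 4.75e-06 and 6.36e-11, and within slide 2 they had 0.00282, 0.0229, 5.95e-06 and 1.5e-09. Adjusted over the list alone, the higher and lower counts were 25 and 5 for phenylpropanoid, 2 and 9 for iron, 19 and 77 for cell cycle and 15 and 122 for ribosomal genes. In all, 6776 probes had a higher and 6472 a lower response in region II than in region I, 2162 and 1717 of them by at least 2-fold. The counts were 5055 and 4972 with the slide as a block and 4409 and 4179 within slide 2.

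From region I to region III the responses of the suberin, phenylpropanoid and laccase lists were shifted up and that of the ribosomal list down, none of them with an estimated correlation. The ammonium transporter Os02g0620600 turned from 1.66 to -6.74, a difference of -8.40 ± 0.34 (adjusted p = 1.25e-06). An isocitrate lyase family gene (Os12g0189300) went from -2.13 to 5.91, a difference of 8.04 ± 0.64 (adjusted p = 2.79e-05), and catalase A (Os02g0115700), which breaks down hydrogen peroxide, from -3.94 to 2.50. An epoxide hydrolase (Os10g0498100) went from 2.80 to -4.50 and the peroxidase Os07g0104500 from 2.09 to -4.77. The slide block gave differences of -8.46, 7.86 and 6.40 for the ammonium transporter, the isocitrate lyase family gene and catalase A. Of 14 suberin genes 7 had a higher response in region III and the other 7 did not pass (median 0.68, adjusted p = 0.0276, adjusted p = 0.548 with an estimated correlation, 0.0235 with the slide as a block and 0.0571 with the replicate number as a block). Of 15 laccases and dirigent proteins 7 had a higher response (median 0.83, adjusted p = 0.0104, adjusted p = 0.548 with an estimated correlation, and 0.0235 with the slide as a block). Phenylpropanoid genes had 24 of 43 members higher and 8 lower (median 0.87, adjusted p = 0.0034, adjusted p = 0.548 with an estimated correlation, and 0.0614 with the slide as a block). Ribosomal proteins had 168 of 245 members lower and 6 higher (median -0.43, adjusted p = 1.29e-13, adjusted p = 0.548 with an estimated correlation, and 8.19e-18 with the slide as a block). The ribosomal counts, adjusted over the list alone, were 7 higher and 181 lower, and those of the other 3 lists were the same. In all, 8077 probes had a higher and 8223 a lower response in region III, 2989 and 2238 of them by at least 2-fold. Regions I and III shared no slide, and with the slide as a block the counts were 3836 and 3715.

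Between regions II and III the isocitrate lyase family gene went from -1.25 to 5.91, a difference of 7.16 ± 0.64 (adjusted p = 0.000445), and the transferase Os10g0122500 from 2.93 to -2.96, a difference of -5.89 ± 0.33 (adjusted p = 8e-05). The cytochrome P450 Os07g0635200 went from 1.03 to -4.17 and a germin-like protein (Os08g0189600) from -3.80 to 1.13. Under the slide block the isocitrate lyase family gene and the transferase had 7.18 and -5.75, and within slide 3 the former had adjusted p = 0.053. Aquaporins and silicon transporters had 8 of 18 members lower and 2 higher in region III (median difference -0.33, adjusted p = 0.0075, and adjusted p = 0.548 with an estimated correlation). Genes of the tricarboxylic acid cycle had 17 of 51 lower and 5 higher (median -0.22, adjusted p = 0.0276, and adjusted p = 0.548 with an estimated correlation). Ribosomal proteins had 33 of 245 members lower and 1 higher (median -0.14, adjusted p = 1.5e-05, and adjusted p = 0.695 with an estimated correlation). Cell cycle genes had 43 of 173 higher and 10 lower (median 0.15, adjusted p = 0.000962, and adjusted p = 0.674 with an estimated correlation). The slide block gave these 4 lists adjusted p = 0.0148, 0.0235, 3.1e-11 and 0.172, and within slide 3 they had 0.0283, 0.0283, 7.11e-10 and 0.206. Adjusted over the list alone, the higher and lower counts were 2 and 8 for aquaporins, 6 and 21 for the tricarboxylic acid cycle and 48 and 11 for cell cycle genes, and 22 ribosomal proteins were lower. In all, 3952 probes had a higher and 3377 a lower response in region III, 930 and 788 of them by at least 2-fold. The counts were 1740 and 1751 with the slide as a block, 523 and 555 within slide 3, and 5441 and 5263 with the replicate number as a block. Without region II replicate 2 they were 2552 and 2167, and the lower count was 2016 without region III replicate 1 and 1957 without replicate 2.

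The change along the root was also compared between region III and region I within each treatment, from the 2 channels taken separately. In aerated roots, RCc2 was lower in region III with a log2 difference of -9.68 ± 0.60 (adjusted p = 8.8e-10), together with a thionin (Os06g0514100, -9.34 ± 0.49), an antimicrobial peptide. A cysteine proteinase (Os08g0556900) was higher by 7.52 ± 0.35 (adjusted p = 2.72e-11). Lsi1 and Lsi2 were higher in region III by 6.07 ± 0.13 and 5.35 ± 0.15. Of 14 suberin genes 11 were higher and 3 lower, with RCN1/ABCG5 up by 2.26 ± 0.16 and CYP86B3 by 2.22 ± 0.20. All 13 iron deficiency genes were higher in region III (median 1.27), of which NAS1 (0.78) turned to -0.33 with quantile normalization and to -0.21 with quantile normalized processed signals. The 3 secondary wall cellulose synthases and BRITTLE CULM1 were higher too (median 1.05). Blocked by slide, Lsi1, Lsi2, RCN1/ABCG5 and CYP86B3 had 6.16, 5.11, 2.45 and 2.18. In region I RCN1/ABCG5 was well above background on 1 of 3 aerated arrays and Lsi2 and Os08g0556900 on 2, and in region III RCc2 was so on 1.

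The counts of list members along the root had no list test. Of 245 ribosomal proteins 230 were lower and 2 higher (median -0.89), and of 173 cell cycle genes 82 were lower and 36 higher (median -0.16). Of 50 expansins 33 were lower and 14 higher (median -1.98), and of 116 peroxidases 63 were lower and 39 higher (median -0.55). The expansin EXPA3 (Os05g0276500) had a log2 difference of -6.86, and the expansin Os04g0228400 was at least 138-fold lower. Other lists with more lower than higher members were glycolysis (34 and 23), the tricarboxylic acid cycle (28 and 12), heat shock proteins (69 and 37) and pectin degradation (23 and 22, with a median of -0.07 that became 0.03 with the processed signals). More members were higher than lower among burst oxidases and metallothioneins (14 and 2), aquaporins (12 and 5), GST (36 and 15), NAC (37 and 7), MYB (66 and 28), WRKY (27 and 8), ERF (25 and 9) and ethylene genes (10 and 3). The same held for auxin (32 and 26), nitrogen (20 and 14), phosphate (15 and 11), lipid transfer (10 and 7), laccase (7 and 6), phenylpropanoid (16 and 14, with a median of -0.02 that became 0.20 with the processed signals), photosynthesis (22 and 19) and fermentation genes (3 and 1). At 2-fold or more the order turned for auxin (17 higher and 20 lower), laccase (2 and 5) and photosynthesis genes (11 and 12), and aquaporins had 4 and 4. Haemoglobins (2 and 2), abscisic acid (9 and 9), jasmonate (8 and 8) and defence genes (22 and 22) were balanced, 1 of 4 ferritins was lower, and neither root hair gene passed.

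In all, 12317 probes were higher and 14141 lower in region III of aerated roots, 5598 and 5211 of them by at least 2-fold. With the slide as a block the counts were 10938 and 12084. These values rest on normalization between arrays, and HB1, higher by 1.21 (adjusted p = 0.0263), did not pass with the slide as a block (0.72, adjusted p = 0.336). It also did not pass without region I replicate 1 (adjusted p = 0.0801) or 2 (adjusted p = 0.0702) or without region III replicate 2 (adjusted p = 0.072) or 3 (adjusted p = 0.096).

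In stagnant roots, CYP86A1 was higher in region III than in region I by 10.47 ± 0.27 (adjusted p = 5.85e-14), and a cationic peroxidase (Os07g0677600), not well above background in region I, was at least 1160-fold higher. CYP86A1 was well above background on 1 of 3 stagnant arrays of region I. Of 14 suberin genes 10 were higher and 3 lower (median 1.58), of 43 phenylpropanoid genes 26 higher and 8 lower (median 0.77). Of 15 laccases 9 were higher and 2 lower (median 0.76), and the 3 secondary wall cellulose synthases and BRITTLE CULM1 were higher (median 2.22). CESA4 and CESA7 were higher by 2.45 ± 0.10 and 2.46 ± 0.13 in stagnant roots, against 1.15 and 1.17 in aerated roots. Lsi1 was higher by 5.06 ± 0.13 and Lsi2 by 1.58 ± 0.15, and PPDKB was lower with -2.39 (adjusted p = 1.48e-05). Under the slide block CYP86A1, CESA7, Lsi1 and Lsi2 had 10.42, 2.61, 5.15 and 1.34.

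Ribosomal proteins had 232 of 245 members lower in region III of stagnant roots and 9 higher (median -1.35), cell cycle genes 103 of 173 lower and 35 higher (median -0.42). Expansins had 34 of 50 members lower and 12 higher (median -1.22) and peroxidases 62 of 116 lower and 37 higher (median -0.76). EXPA3 had a log2 difference of -8.14. Other lists with more lower than higher members were glycolysis (44 and 12), the tricarboxylic acid cycle (31 and 10), heat shock proteins (65 and 46), aquaporins (10 and 7), nitrogen genes (18 and 13, with a median of -0.15 that became 0.07 with the slide as a block), haemoglobins (5 of 6 lower) and ferritins (2 of 4 lower). More members were higher than lower among iron deficiency (11 of 13 higher), burst oxidase and metallothionein (13 and 2), NAC (39 and 8), MYB (72 and 32), WRKY (38 and 11), ERF (25 and 12) and jasmonate genes (16 and 3). This was also so for ethylene (10 and 7), auxin (31 and 29), GST (27 and 20), defence (30 and 16), phosphate (19 and 7), lipid transfer (9 and 6), pectin (27 and 25) and photosynthesis genes (27 and 23). At 2-fold or more the order turned for auxin (12 higher and 21 lower), ethylene (4 and 5), pectin (16 and 17) and heat shock genes (20 and 18), and lipid transfer genes had 5 and 5. Fermentation (2 and 2) and abscisic acid genes (10 and 10) were balanced, and neither root hair gene passed. Adjusted over the list alone, the counts of higher and lower members were the same or differed by at most 2 in both treatments.

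In all, 12416 probes were higher and 14203 lower in region III of stagnant roots, 5755 and 5444 of them by at least 2-fold. With the slide as a block the counts were 11183 and 12270.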

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

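The processing, the tests of each comparison, the gene lists and the rule for named genes were chosen before the data were examined, except list tests of differences and the treatment of descriptions with no hit. Of the tests in this part, those on second probes and on slides for regions I and III were chosen only after the result was seen, and the counts of calls within slides had been seen before the test of slide ratios was run.

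The response to stagnant solution differed between regions by at least 2-fold for 3879 probes in regions I and II, 5227 in regions I and III and 1718 in regions II and III, by limma's test of the difference itself. Calls of at least 2-fold went in opposite directions, with a called difference, for 65 probes in regions I and II (28 rose in region I and 37 in region II), 166 in regions I and III (83 and 83) and 27 in regions II and III (5 and 22). The ammonium transporter Os02g0620600, the isocitrate lyase family gene Os12g0189300 and catalase A (Os02g0115700) were among those of regions I and III.

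The first pattern weighed is that of differences between regions, and slide batch was set against position along the root. Slide batch was taken to shrink differences among arrays of the same slide. The median ratio of the within-slide difference to the full one was 0.99 for 3877 probes of regions I and II (quartiles 0.89 and 1.08). It was 1.01 for 1716 probes of regions II and III (quartiles 0.87 and 1.19), with the same sign for 100% of probes in both. For regions I and III, which shared no slide, the fit with the slide as a block, which links them through region II, gave a median ratio of 1 for 5227 probes (quartiles 0.81 and 1.19), with the same sign for 99.58%. The unscaled standard error of that fit was 1.87 times as large by design. The probes were picked by calls of the full fit, whose regions I and II span slides, so the ratios cannot decide on slide batch. Slide batch and position along the root both stay open.

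The other pattern weighed is that of 1759 probes that changed at least 2-fold in the same direction in all 3 regions, since no dye was swapped. A dye bias of single probes would leave a different probe of the same gene near chance, but of 251 genes with a second probe 99.2% had the same sign on it and 92.43% at least 2-fold in that direction, against 51.39% for random probes. A dye bias that follows GC content would need a trend of a 2-fold size, but the trend had a median size of 0.022 on the log2 scale and at most 0.348 among the 1759 probes, and without it 99.94% of them kept their sign and a mean change of 2-fold. These values argue against both kinds of dye bias as the source of most of the shared response. A dye bias of whole transcripts was not tested, so that the treatment is the source may be said only as a hypothesis.

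Other groupings of the arrays were too few for a share under 0.05. They also put any strong effect into the spread, so their 0 calls decide nothing. With the sign of 1 array turned, 1 of 4 patterns, the real one, gave as many calls: 18975, 22773 and 23100 in regions I, II and III. The highest of the other patterns was 0 (limma, up to 535, 1275 and 504 probes at an unadjusted p under 0.05). Of 10 splits of 6 arrays, 1, the real one, gave as many calls: 13248 for regions II and I, 16300 for III and I, 7329 for III and II, and 26458 and 26619 along aerated and stagnant roots. The highest of the other splits was 0 in each (limma, up to 1873, 853, 3601, 244 and 367 probes at an unadjusted p under 0.05), the 3 other splits that part all same-numbered pairs included.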

How the results depend on the processing

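The value table with its error column, the fits within 1 slide, the slide block for lists and changes along the root, and all settings for lists in differences were chosen only after the results were seen. Of 408 counts under the alternatives 350 stayed within 1.5 times and 58 moved further. Of 8025 values of named genes in regions and differences, 7825 kept their direction and side of the threshold, 189 lost a call, 6 gained one and 5 reversed; along the root 3489 of 3522 did, 23 lost a call, 8 gained one and 2 reversed. Of 1110 list results 1018 did, 74 lost a call, 16 gained one and 2 reversed. Signal over background limits dim genes, some given only as bounds. Unless said otherwise, the cause was not tested.

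A 2-fold minimum, which removes small changes by construction, left 2102 higher and 1399 lower probes in region I, 3681 and 2258 in region II, 3987 and 2176 in region III, 2162 and 1717 for regions II minus I, 2989 and 2238 for III minus I, 930 and 788 for III minus II, 5598 and 5211 along aerated roots, 5755 and 5444 along stagnant roots, and 1115 and 644 shared by all 3 regions. The value table with its error column, which holds only positive values for region I replicate 1, gave 4841 higher and 0 lower probes in region I (limma, 11635 at an unadjusted p under 0.05), 2980 higher for II minus I (of 2980 and 4733 calls 38.6% were higher), 3896 for III minus I (3896 and 6157, 38.8%), 867 and 717 for III minus II, and 2497 higher and 0 lower shared probes.

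With the slide as a block, 7990 probes were higher in region III, the differences had 3836 and 3715 for III minus I and 1740 and 1751 for III minus II, and the shared response 3389 and 2995. Fewer arrays gave fewer calls within slide 2 (4409 and 4179 for II minus I) and within slide 3 (7331 and 5396 in region II, 523 and 555 for III minus II). With only the arrays compared, 2213 probes were lower for III minus II. Median centring gave 9477 shared higher probes.

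With the replicate number as a block, 5263 probes were lower for III minus II against 3377, CESA4 passed in region II (0.15, adjusted p = 0.0468), the fermentation list passed in region II (adjusted p = 0.0477) and the jasmonate list in region I (adjusted p = 0.0166), and the ethylene list of region III (adjusted p = 0.0578), the glutathione S-transferase list of region II (adjusted p = 0.0826) and the suberin list for III minus I (adjusted p = 0.0571) did not. The block changed no other call given in the text and moved no other count by over 1.5 times.

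Of lists, 6, 5 and 5 were shifted higher and 4, 5 and 6 lower in regions I, II and III. An estimated correlation left 0 higher and 1 lower in each region (limma's camera). With median centring 2, 3 and 2 lists were shifted higher, of which the 2 in region I, the tricarboxylic acid cycle (adjusted p = 0.0191) and ribosomal proteins, were not among the 6, and with the slide block 3 in region III. Median centring reversed the cell cycle list (adjusted p = 0.92) and the ribosomal list (adjusted p = 0.00122) in region I, SUS1 in regions II (0.23) and III (0.00), Os01g0575000 in region II (0.23) and Os11g0147000 in regions II (0.08) and III (0.10). The higher NAS1 signal in region III of aerated roots (0.78) reversed with quantile normalization (-0.33) and with quantile normalized processed signals (-0.21). Further calls of lists ended with the processed signals (nitrogen in region II, adjusted p = 0.0625, and ethylene in region III, 0.107), with both channels above background (fermentation in region I, adjusted p = 0.185, glutathione S-transferases in region II, 0.146, suberin in region II, 0.0689, and ethylene in region III, 0.156) and with the mean of probes (auxin and phenylpropanoid in region I, adjusted p = 0.0514 and 0.0731, glutathione S-transferases in region II, 0.0808, and ethylene in region III, 0.0624). The iron list for II minus I and the suberin list for III minus I did not pass with the processed signals (adjusted p = 0.179 and 0.0748).

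Without each replicate in turn, higher and lower probes numbered 7797 to 7957 and 6738 to 6920 in region I, 10499 to 11151 and 9182 to 9866 in region II, 10347 to 10701 and 9356 to 9910 in region III, 5141 to 6194 and 4885 to 6012 for II minus I, 6675 to 7164 and 6497 to 7235 for III minus I, 2552 to 3589 and 1957 to 3094 for III minus II, 11486 to 11891 and 13430 to 13758 along aerated roots, 11686 to 11964 and 13468 to 13746 along stagnant roots, and 4454 to 5589 and 3800 to 4794 in the shared response. Lists shifted higher numbered 2 to 5 in region I (2 without replicate 1 and 3 without replicate 3), 4 to 6 in region II and 4 to 5 in region III, and lists shifted lower 3 to 4, 5 to 5 and 5 to 6.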

Other observations

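The test in this part was chosen before its result was seen, although the counts of list members along the root were known by then.

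Single genes within lists that did not shift as a whole also changed strongly in stagnant roots. Among lipid transfer proteins, Os07g0174900 rose by 3.83 ± 0.21 in region I and 4.84 ± 0.21 in region II, and Os03g0794000 by 2.89, 4.39 and 3.65 in regions I, II and III (SE 0.10). Of the pathogenesis-related genes, a class III chitinase homologue (Os11g0702100) rose by 4.56 and 4.25 in regions I and II (SE 0.23). The phosphate transporter Os03g0150600 rose by 1.11, 2.13 and 2.11 (SE 0.12).

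Among cell wall enzymes, an endoglucanase (Os02g0123700) had log2 ratios of -2.38, -2.89 and -2.46 in regions I, II and III (SE 0.23), while a cellulase (Os10g0545500) rose by 2.79 and 2.31 in regions II and III (SE 0.19). The metallothionein Os12g0570700 had -3.61, -5.05 and -5.05 (SE 0.17), against the rise of the type 3 metallothionein Os01g0200700 by 7.09 in region II. An HSP70 gene (Os03g0277300), a chaperone, rose by 3.48 and 4.62 in regions II and III (SE 0.18), while a small heat shock protein (Os04g0445100) had -2.31, -2.59 and -4.02 (SE 0.16).

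A hypothesis was that stagnant tissue is further along the maturation of the aerated root at the same distance, so that the response of region II might resemble the change from region I to region III of aerated roots. The test set both against each other across 24087 genes, which are not independent replicates, with values from different arrays. The Pearson correlation was -0.09 (Spearman -0.02), where such a resemblance was taken to give 0.3 or more. Of 2051 genes called at least 2-fold in both, 38.32% had the same direction. These values argue against the hypothesis for the response as a whole, and it stays open for single groups such as suberin genes.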
